A study of Homo sapiens with 9 samples.

How the data were processed

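RNA was measured in 9 cultures of K562, a human erythroleukaemia cell line derived from chronic myeloid leukaemia: the parental line, 4 CRISPR clones with wild-type SRSF2 (WT clones) and 4 CRISPR clones with the P95H substitution in SRSF2 (P95H clones). Per the labels' protocols, total RNA was purified with a miRNeasy kit, polyadenylated RNA was selected, libraries were made with a TruSeq RNA kit and sequencing was done on a HiSeq2000. Group and clone were taken from the sample titles. Each clone is 1 library, so p-values measure the spread between clones, and the labels do not say whether clones of a group came from separate editing events.

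The deposited values are raw read counts per Ensembl gene, with no normalization. Per the submitters' processing notes, bcl2fastq, TopHat2 2.0.4 and HTSeq 0.6.1p1 were used with genome build GRCh37, and the gene IDs carry the Ensembl release 75 annotation according to the file labels. The alignment settings, the overlap mode of counting and the strand setting are not given in the sources used here. The kit named does not mark strand. In 264 pairs of a gene and an antisense partner with at least 90% of the partner inside the gene's exons, the median ratio of their read densities was 2.05 (quartiles 1.09 and 3.21), and reads of a gene and of its antisense partner were therefore treated as not separable. Reads with several alignments were left out of the counts by the counter, so genes with near-identical copies, such as HBG1 and HBG2, RPL39L and the NPIP family, are less certain.

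The 5 summary values at the end of each count list were kept out of library sizes and tests. They held reads placed in no gene by the counter (47.6 to 49.1% of all reads listed) and ambiguous reads (2.23 to 2.55%). Reads aligned more than once made up 5.06 to 6.06%, which left 43.3 to 44.2% assigned to genes. As the strand setting is not given, reads placed in no gene may include reads from within genes, on the other strand. Of the gene IDs, 35744 had a count in at least 1 library and 52526 had a symbol. Symbols, biotypes and chromosomes came from GENCODE 29 (GRCh38) by gene ID. Because that build is not the one of the counts, no coordinates are given and positions were used only for the chromosome and the order of genes.

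The main test of P95H against WT clones was edgeR 4.0.16 (R 4.3.3): genes kept by filterByExpr, TMM scaling, robust quasi-likelihood fit and F test, and Benjamini-Hochberg adjustment over all genes tested with a threshold of 0.05. The parental library was compared with the WT clones in a 3-group model of all 9 libraries, in which the lone library is assumed to vary like the clones. Each clone was also set against the other clones of its group in the same way. Levels are given as CPM, counts scaled to a common library total after TMM scaling, log2 CPM used a prior count of 2, and principal components used the 500 most variable genes. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. Each list's mean log2 CPM per clone was also compared by a two-sided exact permutation test over 70 labelings, whose smallest possible p is 0.0286. For whole lists, 863 entries in 37 lists were fixed and 851 matched a gene ID. They covered splicing factors and kinases, nonsense-mediated decay, polycomb and HOX genes, reported targets of mutant SRSF2, erythroid, megakaryocyte, myeloid, mast cell, lymphoid and progenitor markers, markers of fibroblasts and epithelia, cell cycle, DNA damage, apoptosis, stress, metabolism, ribosome, histones, immunity and signalling.

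The groups, the edgeR tests of P95H against WT clones, of the parental library and of single WT clones, the camera tests, the lists, the rule for genes to name and most alternatives were fixed before the data were examined. The alternatives were RLE and upper quartile scaling, no filter and a stricter filter (1 CPM in 4 libraries), DESeq2 1.42.0, limma-voom with quality weights, a 3-group fit, the parental library counted as wild type, 1 surrogate variable (sva 3.50.0), glmTreat against a fold of 1.2, and each clone left out in turn. Chosen after seeing the data were the tests of single P95H clones, the permutation test of list means, the search along chromosomes, the search for genes far out in 1 library, the thinning of counts, the removal of a trend over GC content and gene length, leaving out W33 and P22 together, leaving out chromosomes 1 and 11, and leaving W33 out of the comparisons of single clones. The rule for naming asked for SRSF2, then up to 12 protein-coding genes in each direction past the threshold with a mean of at least 1 CPM and no overlap between the groups, and up to 4 genes per list by p. As no gene passed, genes called by both DESeq2 and limma-voom under the same conditions were named instead, a choice made after the values were seen.

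For neighbouring genes, 9842 genes with a mean of at least 5 CPM were placed in order in bins of 40, after the trend over GC content and length had been removed, and runs of at least 5 bins with a median log2 ratio of at least 0.2 in size were taken. To test the parts, they were sought again in every other gene with the trend kept and measured in the genes left over with it removed. For a test of depth, counts of the 8 clones were drawn at random down to the total of W33. Libraries far from the other 3 of their group were sought with Dixon's ratio in 230 groups of 4 values. The values were levels of named genes, list medians and measures of the libraries, such as read totals. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots.

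The main test was tested on simulated data for P95H against WT clones over 18173 genes. edgeR recovered 8.96% of genes changed 1.5-fold, 49.3% of those changed 2-fold and 87.9% of those changed 4-fold, with 1 false call among 98. limma-voom recovered 8.96%, 43.3% and 84.8%, with 1 false call among 92. DESeq2 recovered 28.4%, 70.1% and 93.9%, with 42 false calls among 170. The changed genes all had a mean over 1 CPM, and each gene had the same spread in all libraries. No library was made to stand apart as W33 does. These shares therefore do not cover genes at lower levels or a library like W33. A list planted with a 1.3-fold change was found by camera (adjusted p = 4.21e-13) and 0 other lists were called. Each gene was drawn on its own in these counts, so they cannot show how often camera calls lists whose genes move together between clones. In the search along chromosomes, 20 of 20 planted parts were found and 20 shuffles of gene order gave 0 runs. Exon usage, splicing and DNA sequence were not analysed here, and the levels of a few genes are not reported here.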

Results

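Gene expression was measured in the parental K562 line, in 4 WT clones (W19, W33, W36 and W42) and in 4 P95H clones (P9, P15, P22 and P38). K562 is an erythroleukaemia line that makes embryonic and fetal globin, and SRSF2 encodes a serine- and arginine-rich splicing factor in which P95H recurs in myeloid neoplasms. The series was set up to examine splicing in clones with mutant or unmutated SRSF2. The counts analysed here are per gene, so the question addressed is which genes differed in level. Reads counted in genes came to 35477328 in the parental library, 26835296 in W19, 24546255 in W33, 30902602 in W36, 26658948 in W42, 25208033 in P9, 32351553 in P15, 32593383 in P22 and 30407317 in P38. At these depths 3 counts, taken as the floor, corresponded to 0.0846 to 0.122 CPM, a limit that covers counting error only.

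SRSF2 itself (ENSG00000161547, chromosome 17) stood at 489.6 ± 32.1 CPM (SD, n = 4) in WT clones and 502 ± 62.8 CPM (n = 4) in P95H clones. The log2 difference was 0.04 (SE 0.11) with an edgeR adjusted p of 0.917, and leaving out any 1 clone gave -0.04 to 0.08. The counts do not separate the 2 alleles, and SRSF2 shares its locus with the antisense gene MFSD11.

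In the P95H clones, 2 genes of the red cell lineage lay above all WT clones. AQP1, the water channel of the red cell membrane, averaged 37.1 ± 20.1 CPM against 8.37 ± 4.14 CPM (log2 2.15, SE 0.42), and CA1, a carbonic anhydrase of red cells, 2.64 ± 0.982 against 0.270 ± 0.408 CPM (log2 3.35, SE 0.83, and 5.17 without W33). SAT1, which acetylates polyamines, stood at 44.2 ± 11.7 against 19.1 ± 3.39 CPM, PPARA, a nuclear receptor of lipid metabolism, at 16.6 ± 2.95 against 8.52 ± 1.25 CPM, and TNRC6C, a partner of Argonaute in microRNA silencing, at 16.9 ± 3.10 against 8.26 ± 0.910 CPM. Lower in all P95H clones than in any WT clone were CILP2 (1.48 ± 0.888 against 12.1 ± 6.75 CPM, log2 -3.03, SE 0.53), GNB1L (24.3 ± 5.11 against 54.5 ± 12.2 CPM), ALG8, a glucosyltransferase of N-glycan assembly (55.6 ± 9.99 against 93.6 ± 3.32 CPM), and C5AR1, the receptor of complement C5a (1.08 ± 0.432 against 2.51 ± 0.394 CPM). Each mean is over 4 clones with its SD.

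Other genes higher in all P95H clones were SERPINC1, which encodes antithrombin (log2 2.11, SE 0.51), TNXB (1.59), ZNF304 (1.36), KLHL3 (1.31), CACNA1F (1.27), CPE (1.24) and ZNF226 (1.19). Others lower were SYPL2 (log2 -2.29, SE 0.37), TMEM145 (-1.25), GLB1L2 (-1.07), SEMA6B (-1.05), SLC4A11 (-1.02), RPL39L (-0.86), HSD17B7, an enzyme of cholesterol synthesis (-0.79), and KLHL17 (-0.78). TNXB, ZNF304, TNRC6C and GNB1L each overlap a gene on the other strand (CYP21A2, ENSG00000268678, TNRC6C-AS1 and TBX1), so their reads are shared. The same holds, in this and the other parts of the text, for ALAS2 (APEX2), CASP6 (MCUB), GAS5 (GAS5-AS1), GP6 (GP6-AS1), HLA-B (ENSG00000271581), HSP90B1 (UQCC6), LSS (ENSG00000223901), PDIA6 (ATP6V1C2), SIGLEC6 (ENSG00000268777), SLC7A5 (ENSG00000260466), SMO (ENSG00000243230), SNHG12 (TRNAU1AP), TUBB1 (ATP5F1E) and U2AF2 (ENSG00000267523). ALG8 and GLB1L2 lie in the part of chromosome 11 whose genes were lower as a block in P15, and SYPL2 in the part of chromosome 1 whose genes were lower as a block in P9.

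None of these genes passed the main test. edgeR tested 18173 genes and called 0 at an adjusted p under 0.05, or at 2-fold (smallest adjusted p 0.128), with 2130 genes at an unadjusted p under 0.05 (1103 higher and 1027 lower in P95H clones) where 909 would be so by chance. DESeq2 called 269 genes (156 higher, 113 lower; 125 of them at least 2-fold) and limma-voom with quality weights 59 (38 higher, 21 lower; 28 at least 2-fold). The 24 genes above are the 12 highest and 12 lowest in log2 difference among 40 protein-coding genes called by both, picked after their values were seen. DESeq2 and limma-voom called 53 genes in common, 32 higher and 21 lower. For AQP1 the adjusted p was 0.256 in edgeR, 6.15e-05 in DESeq2 and 0.0385 in limma-voom, and for GNB1L 0.220, 7.95e-05 and 0.0327. The values of the 4 P95H and 4 WT clones did not overlap at 1544 genes, 8.496% of those tested, against 2.86% by chance. The biological coefficient of variation between clones of a group was 26.3%. With W19 left out edgeR called 1 gene, NPIPA3 (lower, adjusted p = 0.0274), and with W33 and P22 left out 5 genes, all higher: CA1, TNRC6C-AS1, and the erythroid genes ADD2, HBD and HBBP1, chosen for naming because they were so few.

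**Figure D1:**
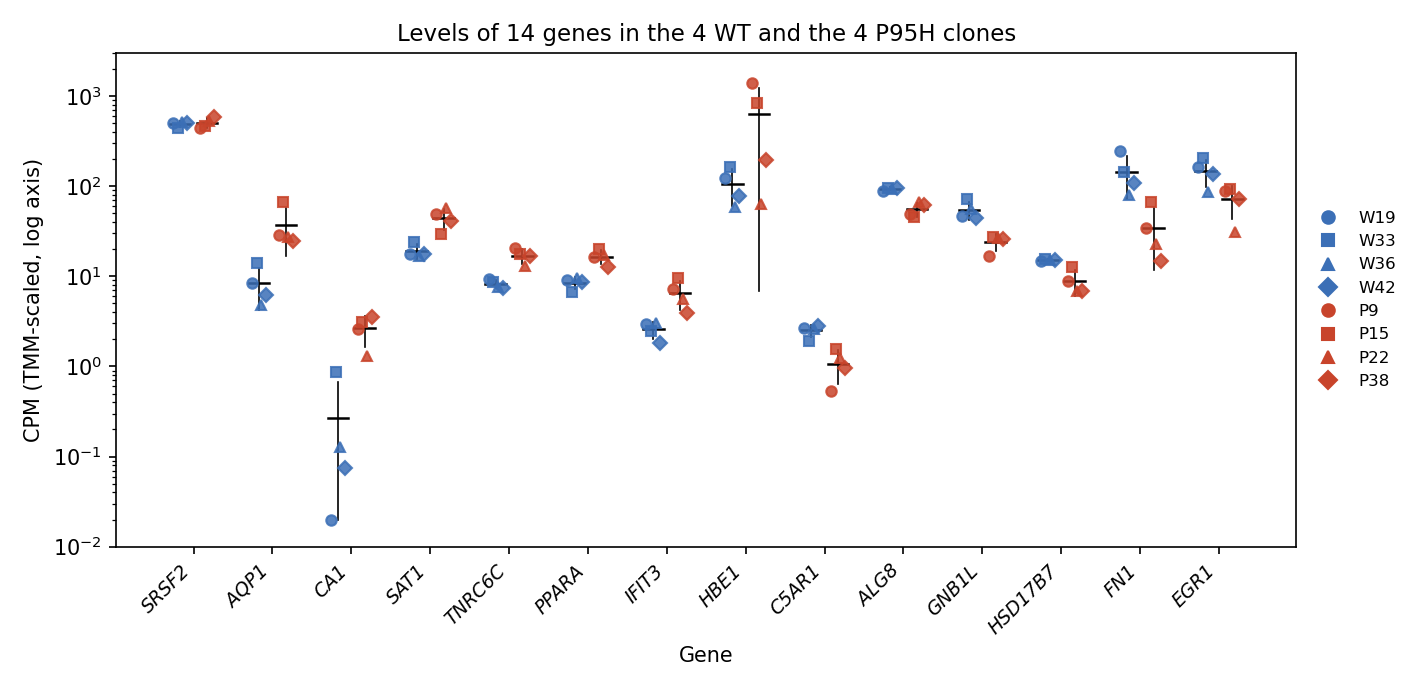
CPM on a log axis of 14 genes in each WT clone (blue) and P95H clone (red), with the mean (horizontal bar) and SD (vertical line) of each group of 4. The groups overlap for SRSF2, AQP1 and SAT1 lie higher and ALG8 and GNB1L lower in the P95H clones; CA1 in W19 has 0 counts and is drawn at 0.02 CPM, where lower error bars also end.

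Interferon-response genes were higher in P95H clones: 15 of 19 measured members lay above 0, with a median log2 difference of 0.76, and the list rose in camera at the preset correlation (adjusted p = 0.000285). With an estimated correlation it did not pass (adjusted p = 0.514). OAS3, which senses double-stranded RNA, averaged 7.70 ± 4.82 against 2.17 ± 0.459 CPM, IFIT3 6.57 ± 2.39 against 2.58 ± 0.561 CPM and STAT2, a transcription factor of the pathway, 56.9 ± 17.7 against 31.2 ± 4.95 CPM (SD, n = 4). These 3 genes passed when adjusted over the list alone and 0 did over all genes. All 4 P95H clones had a list median above that of every WT clone, from 0.27 in P38 to 1.13 in P15 relative to the WT mean. By the mean log2 CPM of the list, 3 of 4 P95H clones lay above every WT clone, with an exact permutation p of 0.0571 (0.264 after adjustment).

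Genes of the red cell membrane were higher in 3 of the 4 P95H clones. In this list 19 of 23 measured members lay above 0 (median log2 0.39, camera adjusted p = 0.00576), among them AQP1, ADD2, an adducin of the membrane skeleton (105 ± 27.2 against 60.6 ± 11.4 CPM), EPB42 (2.22 ± 0.850 against 1.03 ± 0.285 CPM) and SLC4A1, the anion exchanger band 3 (3.85 ± 5.56 against 0.413 ± 0.220 CPM), which was at 12.16 CPM in P15 and 0.425 to 1.495 CPM in the other P95H clones (log2 3.23, and 1.40 without P15). The call was lost with an estimated correlation (adjusted p = 0.794) and without P15 (adjusted p = 0.396). AQP1 and ADD2 passed when adjusted over the list alone and 0 genes over all genes. The list median was 1.05 in P15, 0.46 in P9 and 0.27 in P38 but -0.54 in P22, a clone with low HEMGN and HBD (values with the single clones). Without P22 the camera adjusted p was 3.43e-09, at the preset correlation of 0.01. With all 8 clones the correlation of this list was estimated at 0.557.

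Globins and heme synthesis did not pass with all 8 clones (camera adjusted p = 0.310 and 0.0620). Embryonic HBE1 averaged 624 ± 617 CPM in P95H and 106 ± 46.8 CPM in WT clones, HBG2 2319 ± 830 against 1570 ± 514 CPM, HBG1 906 ± 352 against 600.0 ± 189 CPM, and ALAS2, the first enzyme of heme synthesis in red cells, 293 ± 294 against 55.0 ± 52.1 CPM. HBE1 was at 1396 CPM in P9, 841 CPM in P15, 195 CPM in P38 and 63.3 CPM in P22. Its log2 difference of 2.55 was 1.77 to 2.92 with 1 clone left out. Without P15 the log2 difference of ALAS2 fell from 2.42 to 1.43 and that of HBG1 from 0.60 to 0.37. The list median of globins was 0.80 in P9, 1.003 in P15 and 0.72 in P38, but -0.64 in P22, and it was 0.73 in the WT clone W33. Leaving out P22 or W33 gave adjusted p = 0.000379 or 0.0157 for globins and 0.00106 or 0.00910 for heme synthesis, in both cases higher in P95H clones and at the preset correlation. With all 8 clones the correlation was estimated at 0.744 for globins and 0.0888 for heme synthesis, and the adjusted p with it was 0.859 and 0.644. The β-like globin genes lie in the part of chromosome 11 whose genes were higher as a block in P15.

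Cholesterol synthesis fell in 3 of the 4 P95H clones, with 20 of 23 genes below 0 (median log2 -0.38, camera adjusted p = 1.87e-05 at the preset correlation). With an estimated correlation it did not pass (adjusted p = 0.514). DHCR7, the last enzyme of the pathway, averaged 75.1 ± 15.3 against 111 ± 5.21 CPM, HSD17B7 8.83 ± 2.78 against 15.3 ± 0.315 CPM and LSS, lanosterol synthase, 80.3 ± 19.3 against 111 ± 11.2 CPM. DHCR7 lies in the part of chromosome 11 that was lower in P15. SQLE, squalene epoxidase, went the other way (271 ± 62.6 against 177 ± 26.5 CPM, log2 0.61). HSD17B7 and DHCR7 passed when adjusted over the list alone, and 0 genes over all genes. The median of the list was -0.64 in P22, -0.39 in P38 and -0.33 in P9 but -0.02 in P15, within the range of the WT clones.

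Genes of the unfolded protein response fell as a list (13 of 18 below 0, median -0.26, camera adjusted p = 0.000236, 0.514 with an estimated correlation). The chaperone HSP90B1 averaged 535 ± 105 against 768 ± 47.7 CPM, the disulfide isomerase PDIA6 359.9 ± 35.6 against 481 ± 19.5 CPM and SDF2L1 163 ± 25.9 against 262 ± 97.6 CPM (log2 -0.68, and -0.39 without W33); HSP90B1 and PDIA6 passed when adjusted over the list alone and 0 genes over all genes. All 4 P95H clones had list medians below every WT clone (-0.35 to -0.14). Glycolysis and hypoxia genes fell as well (20 of 28 below 0, median -0.19, camera adjusted p = 0.000236, 0.514 with an estimated correlation), with PKM, pyruvate kinase, at 606 ± 138 against 927 ± 133 CPM and the glucose transporter SLC2A3 at 88.5 ± 22.4 against 129.5 ± 2.99 CPM. In that list 0 genes passed over all genes or adjusted over the list alone.

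Heat shock genes (17 of 18 below 0, median -0.16), core spliceosome genes (28 of 38 below 0, median -0.16) and amino acid response genes (20 of 24 below 0, median -0.15) fell with camera adjusted p = 0.00576, 0.00576 and 0.0233. With an estimated correlation the adjusted p was 0.514, 0.644 and 0.809. STIP1, a co-chaperone of HSP90, averaged 401 ± 66.6 against 491 ± 27.9 CPM (log2 -0.29, and -0.18 without P15) and CHORDC1 54.1 ± 11.5 against 76.8 ± 13.98 CPM; both lie in the part of chromosome 11 that was lower in P15. U2AF2, which binds the polypyrimidine tract, averaged 273 ± 14.8 against 321 ± 4.87 CPM, SF3B5 155 ± 14.7 against 241 ± 80.9 CPM (log2 -0.64, and -0.38 without W33) and SNRPA1 27.9 ± 3.10 against 37.72 ± 5.43 CPM. In these 3 lists 0 genes passed over all genes or adjusted over the list alone. Without W33, whose spliceosome genes had a median of 0.28 above the WT mean, the adjusted p was 0.0638, 0.06 and 0.0596. For amino acid genes such as SLC7A5 (171 ± 28.6 against 225 ± 25.3 CPM) and PSPH (14.8 ± 3.65 against 19.955 ± 2.88 CPM) the call was also lost without W36, P22 or P38: the camera adjusted p of the list amino acid response was then 0.217, 0.643 and 0.0783, and 0.069 with the trend over GC content and length removed. Its median was 0.37 in P15.

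Markers of fibroblasts and epithelia, 8 of 20 measured, fell (7 of 8 below 0, median -0.68, camera adjusted p = 0.000707). The adjusted p was 0.514 with an estimated correlation and 0.218 without W33 and P22. FN1, fibronectin, averaged 34.7 ± 23.1 against 144 ± 72.5 CPM, the surface protein EPCAM 78.4 ± 45.3 against 127 ± 31.9 CPM (log2 -0.70, and -1.14 without P38) and the mucin MUC1 9.62 ± 1.66 against 14.4 ± 2.79 CPM. FN1 and MUC1 passed when adjusted over the list alone and 0 genes over all genes. In the parental library FN1 was at 8.51 CPM, below the mean of either group. The median was -1.85 in P22 and -0.60 to -0.44 in the other 3 P95H clones.

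Splicing regulators other than the core spliceosome did not pass as lists: camera adjusted p was 0.869 for SR proteins, 0.873 for hnRNP proteins and 0.381 for splicing kinases, whose median was 0.05 to 0.18 in P95H and -0.22 to 0.15 in WT clones. SRSF6 averaged 257 ± 31.7 against 211 ± 8.20 CPM and HNRNPC 666 ± 43.8 against 824 ± 63.3 CPM, neither past the test over all genes. The nonsense-mediated decay machinery (0.587) and transcripts known to be its substrates (0.572) did not pass either; of the latter SNHG12 stood at 112 ± 39.6 against 71.1 ± 2.74 CPM and GAS5 at 402 ± 95.6 against 306 ± 30.5 CPM, and without P38 their log2 differences fell from 0.66 to 0.39 and from 0.39 to 0.22. Among reported targets of mutant SRSF2 (0.444) were EZH2, the polycomb methyltransferase, at 155 ± 11.4 against 173 ± 15.4 CPM (log2 -0.16, edgeR adjusted p = 0.571), CSF3R at 4.59 ± 3.64 against 1.35 ± 0.498 CPM (9.975 CPM in P22 and 2.22 to 3.55 CPM in the other P95H clones; log2 1.77, and 1.04 without P22) and FYN at 41.2 ± 7.98 against 28.6 ± 4.43 CPM. CSF3R and FYN passed when adjusted over the list alone. CSF3R and SNHG12 lie in the part of chromosome 1 that was lower in P9. Isoforms of these genes were not analysed here.

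Of the other lists, camera adjusted p was 0.101 for megakaryocyte and platelet genes, 0.129 for erythroid transcription factors, 0.161 for MYC and its partners, 0.261 for HOX genes, 0.321 for antigen presentation, 0.379 for BCR-ABL and JAK-STAT signalling, and 0.381 for each of cytosolic ribosomal proteins, replication-dependent histones, NF-kB and inflammatory genes, apoptosis regulators and the DNA damage response. It was 0.418 for stem and progenitor genes, 0.449 for S phase, 0.734 for polycomb complexes, 0.948 for each of p53 targets, mitochondrially encoded genes, lymphoid markers and myeloid markers, 0.972 for G2/M phase and 0.988 for mast cell and basophil genes. Adjusted over the list alone, genes that passed were TUBB1 (megakaryocyte), MXD1 and CAD (MYC list), CD7 (lymphoid) and 2 apoptosis regulators, CASP6 among them, all higher in P95H clones, while over all genes 0 members of any list passed. The camera adjusted p of the list cytosolic ribosomal proteins was 0.00268 without W33, where the direction turned from lower to higher in P95H clones, and 0.0188, 0.0146 and 0.00738 without W19, W42 and P38, where they were lower. Erythroid transcription factors passed without W33 (0.0287), megakaryocyte genes without P15 (0.0273) or P22 (0.0367) and the MYC list without P38 (0.0272). These values are at the preset correlation; with all 8 clones and an estimated one the adjusted p was 0.991 for ribosomal proteins, 0.514 for erythroid transcription factors and for megakaryocyte genes, and 0.741 for the MYC list. Median and mean had opposite signs, with camera's direction down, for BCR-ABL signalling (0.06 and -0.13), lymphoid markers (-0.20 and 0.17), myeloid markers (-0.06 and 0.36) and G2/M phase (-0.00879 and 0.00123). For p53 targets both were above 0 while camera's direction was down.

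Across the 37 lists, camera thus called 9 with the preset correlation, 2 higher and 7 lower. With an estimated correlation 0 were called (smallest adjusted p 0.514), with fry 0 by direction (0.184) and 3 for change in either direction: the unfolded protein response, the markers of fibroblasts and epithelia and the reported SRSF2 targets, each at 0.0389. An exact permutation test of each list's mean per clone gave the smallest possible p, 0.0286, for 5 lists, of which the smallest adjusted p was 0.211.

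**Figure D2:**
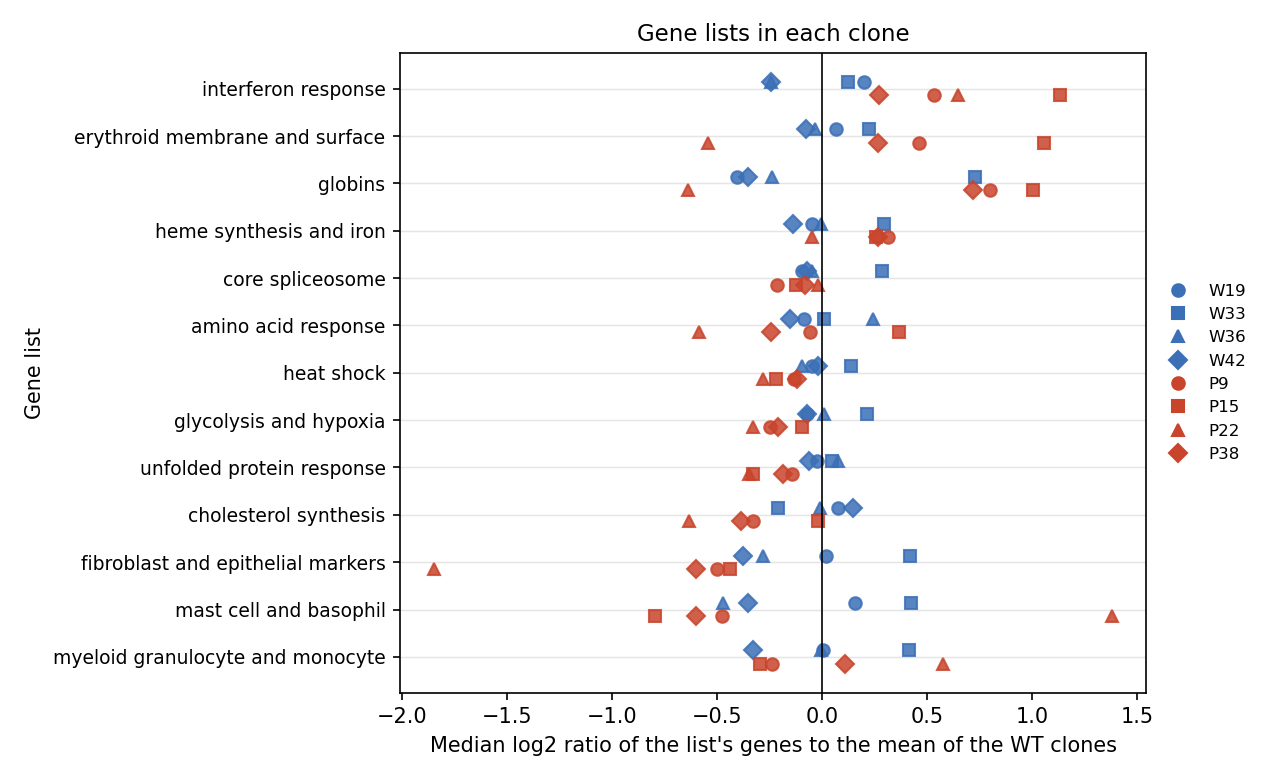
Median log2 ratio to the mean of the WT clones for the measured genes of 13 lists, 1 symbol per WT clone (blue) and P95H clone (red). All P95H clones lie above the WT clones for interferon response and below them for the unfolded protein response, whereas P22 lies apart from the other P95H clones for erythroid, globin, mast cell and fibroblast lists.

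Compared with the WT clones, which asks what editing and cloning left in cells with unmutated SRSF2, the parental library had much more KYNU, an enzyme of tryptophan breakdown (6.78 CPM from 235 counts, against 0.0405 ± 0.0366 CPM from 4 counts over the 4 WT clones). It was the single gene called by edgeR among 20636 (adjusted p = 0.0144) and lies outside the naming rule because its mean was under 1 CPM. In the parental library H19, an imprinted non-coding RNA, stood at 16.2 CPM against 125 ± 29.7 CPM, the immediate early genes EGR1 and FOS at 20.3 against 148 ± 50.5 CPM and 1.36 against 8.16 ± 2.82 CPM, and FN1 at 8.51 against 144 ± 71.7 CPM. These 4 genes, and KYNU, PAGE5 (5.31 against 0.0619 ± 0.0626 CPM) and DEUP1 (2.77 against 0.0558 ± 0.0367 CPM), which were higher, were called by DESeq2, 7 in all. They were named because they are few, after their values were seen. The P95H clones lay between for H19 (64.5 ± 15.1 CPM), EGR1 (70.9 ± 28.1 CPM), FOS (3.10 ± 1.27 CPM) and FN1 (34.5 ± 22.9 CPM).

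At an unadjusted p under 0.05, 354 genes differed between the parental library and the WT clones (191 higher, 163 lower), fewer than the 1032 that chance would give. The parental line has 1 library and no replicate check. Without W19 or W42, with the stricter filter, or with only the parental library and WT clones in the fit, edgeR called 0 genes (232, 340, 175 and 586 at an unadjusted p under 0.05), and without W33 or W36 it called 1 (1179 and 277, the first more than 1032). No filter on low counts gave 5: KYNU, PAGE5, DEUP1 and NTS higher and H19 lower.

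Single clones differed in very different measure from the others of their group. W33 differed from the other WT clones at 2457 genes in edgeR (1119 higher, 1338 lower), W42 at 4 and W19 and W36 at 0 (80 and 95 genes at an unadjusted p under 0.05; no other tool was run). The 4 genes lower in W42 were MAGED1 (1.70 against 51.2 ± 10.996 CPM), HCLS1, a haematopoietic signalling adaptor (1.07 against 37.68 ± 4.70 CPM), ADGRA3 (0.924 against 13.3 ± 1.60 CPM) and LINC01524, with 0 counts in W42 and 1.78 ± 0.323 CPM in the other 3 WT clones. Among P95H clones P22 differed at 67 genes (46 higher, 21 lower), P15 at 1, the pseudogene ENSG00000231747, and P9 and P38 at 0 (721 and 423 at an unadjusted p under 0.05). With W33 left out of the fit, P22 had 182 calls, P15 24, P9 1 and W42 3. After a trend over GC content and gene length was removed W33 had 773 calls, 622 of them among the 2457 and in the same direction, and P22 had 104, 65 of them among the 67.

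Some of the genes that differed in P22 are given here. KIT, the receptor of stem cell factor, stood at 36.4 against 1.04 ± 0.557 CPM in the other 3 P95H clones, CD53 at 156 against 8.64 ± 3.98 CPM, DOCK2 at 127 against 6.28 ± 4.001 CPM, SPI1, the transcription factor PU.1, at 57.5 against 15.4 ± 1.74 CPM, SIGLEC6 at 44.7 against 2.91 ± 0.246 CPM and APOBEC3G at 73.3 against 5.17 ± 0.778 CPM. KDM1A, a histone demethylase, stood at 622 against 309 ± 29.7 CPM. Lower in P22 were the red cell genes HEMGN, at 41.5 against 234 ± 43.8 CPM, and HBD, at 3.09 against 17.1 ± 0.936 CPM. PTPRC, the leukocyte antigen CD45, was at 0.182 against 129 ± 18.7 CPM. All of these had an edgeR adjusted p under 0.05 (0.000500 for SIGLEC6, 0.0492 for SPI1 and PTPRC) and were picked from the 67 after their values were seen. List medians in P22, relative to the WT mean, were 1.38 for mast cell and basophil genes (4 of 12 measured), 0.58 for myeloid markers (13 of 25 measured), 0.16 for erythroid transcription factors, -0.54 for erythroid membrane genes and -0.64 for globins; lists were not tested in P22 alone. Of the 4 mast cell genes, KIT and HDC (3.12 CPM, others 0.307 to 0.373) carried the median, while GATA2 (109.8 CPM, others 65.3 to 100.4) and MS4A2 (0.394 CPM, others 0.0933 to 1.57) lay closer to or within the range of the other P95H clones. HDC was also at 2.94 CPM in the WT clone W33, so its level is not particular to P22.

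The median SD of log2 CPM over 15629 genes was 0.247 in the WT and 0.215 in the P95H clones. Without W33 the WT value was 0.115, and without P22 the P95H value was 0.203. The first principal component (32.7% of variance) set P22 apart (54.3, next the parental library at 20.1), the second (17.6%) W33 (37.9) and the third (16.2%) P15 (38.6). A trend over GC content and gene length accounted for 19.96% of the variance of log2 ratios between genes in W33, 10.9% in W42, 7.44% in P38 and 3.98% in P9, and at most 2.47% in the other 5 libraries.

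**Figure D3:**
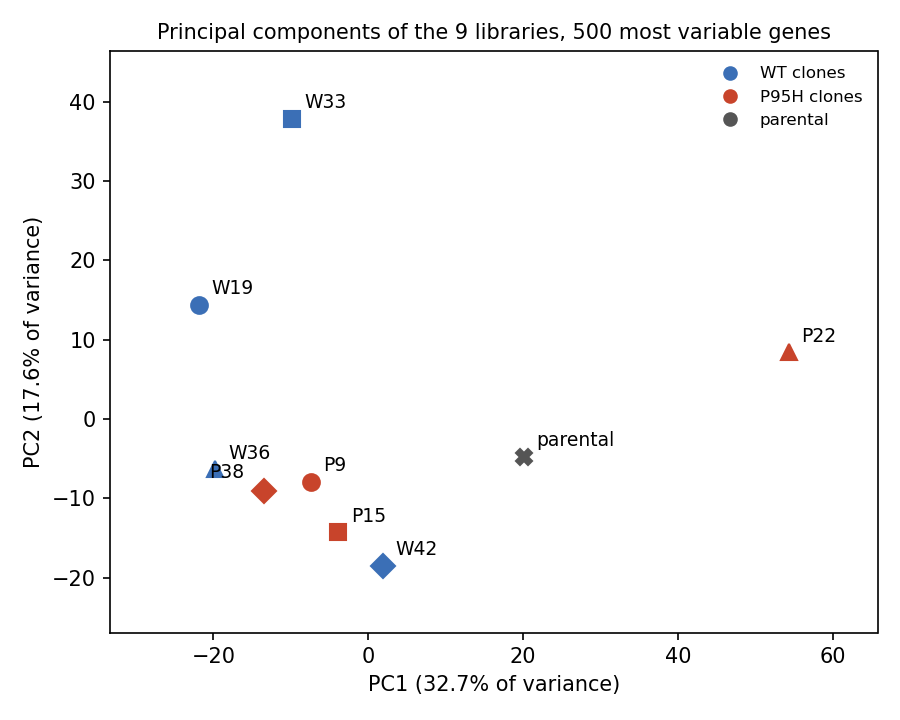
Principal components 1 and 2 (arbitrary units, with their share of variance) of log2 CPM over the 500 most variable genes in the 9 libraries, with WT clones in blue, P95H clones in red and the parental line in grey. P22 lies at 54.3 on the first and W33 at 37.9 on the second component, and the other P95H clones lie among the WT clones.

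Genes next to each other on a chromosome shifted together in 3 clones. In P15, 215 expressed genes of chromosome 11 from BET1L to ZFP91 had a median log2 ratio of 0.43 to the other libraries (89.3% above 0), and the 375 that follow, from OSBP to GLB1L2, a median of -0.54 (94.7% below 0). In P9, 504 genes of chromosome 1 from TPRG1L to LAMTOR5 had a median of -0.40 (91.5% below 0). In W33, 210 genes of chromosome 1 from TPRG1L to FAM229A had a median of -0.32 (83.8% below 0), which was -0.16 when the trend over GC content and length was kept. In the other 8 libraries the median over the same genes was -0.04 to 0.00 and 0.00 to 0.08 for the parts in P15, -0.23 to 0.05 for that in P9 and -0.36 to 0.06 for that in W33, where P9 and W33 share the start of chromosome 1. With the trend over GC content and length removed, W33 also lay low in bins 8, 10, 12, 13 and 14 of chromosome 17 (-0.21, -0.29, -0.25, -0.44 and -0.36). Bins 9 and 11 were under 0.2 in size (-0.09 and -0.16), so this stretch missed the rule for runs. SRSF2 is on chromosome 17 too, and its place among these bins was not examined. DNA was not measured here. The planned test of calls by chromosome gave no value because edgeR called 0 genes.

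**Figure D4:**
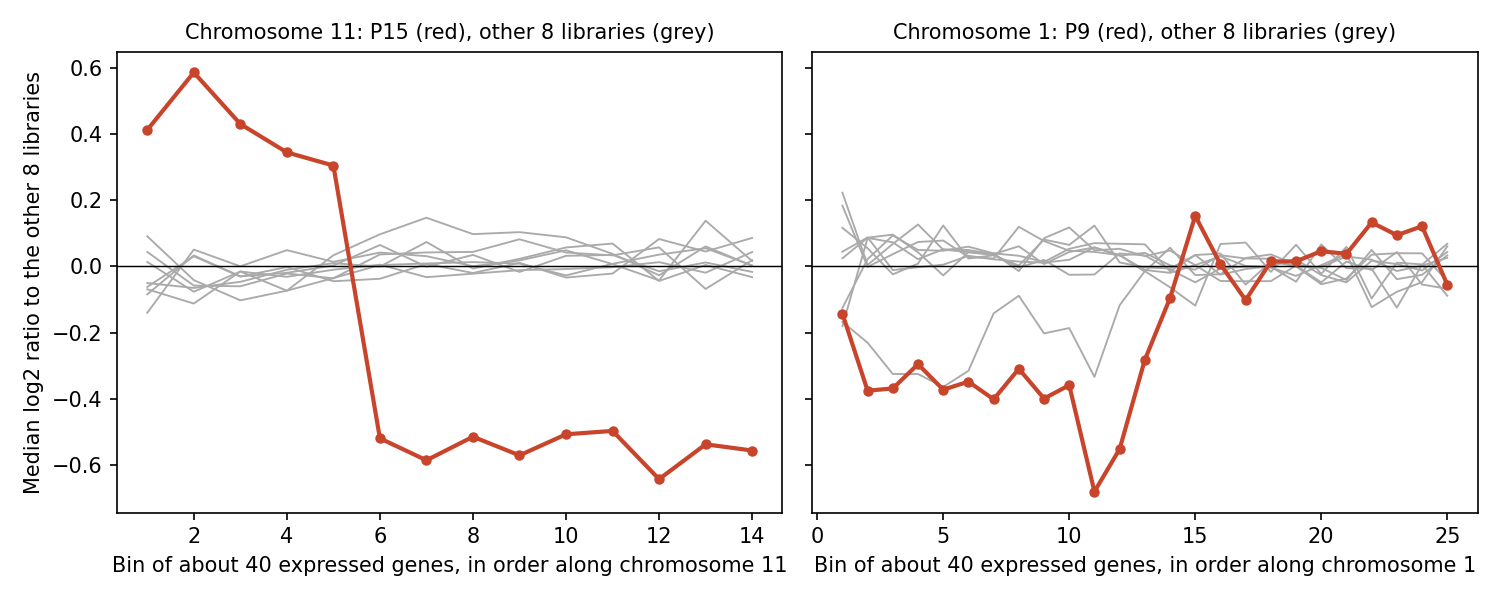
Median log2 ratio to the other 8 libraries in bins of about 40 expressed genes, in gene order along chromosome 11 (left, P15 in red) and chromosome 1 (right, P9 in red), with the other 8 libraries in grey. P15 lies at about 0.43 and then -0.54 on chromosome 11, P9 at about -0.40 over its part of chromosome 1, and the low grey line on chromosome 1 is W33.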

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

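The tests of GC content, depth and abundant genes in W33, those of the parts of chromosomes and all 3 tests of P22 were chosen or changed after the result was seen, as was the search for libraries far from the other 3.

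Libraries that stood far from the other 3 of their group were found in 22 of 230 groups tested, where about 5% would be so by chance. The same clones make up all these groups, so the groups are not independent. W33 was lowest among WT clones for SRSF2 (441.5 CPM, others 504 to 508), STAT2 (23.9, others 32.7 to 34.8), U2AF2 (314, others 323 to 324), EZH2 (150.1, others 179 to 184) and MXD1 (13.5, others 20.1 to 21.4), and highest for SAT1 (24.2, others 17.0 to 17.7), UROS of heme synthesis (27.0, others 15.7 to 16.4) and SF3B5 (362, others 192 to 212). Its list medians, relative to the WT mean, were highest for core spliceosome (0.28), globins (0.73) and lymphoid markers (0.86) and lowest for polycomb complexes (-0.19). P22 was lowest among P95H clones for HBD (3.09 CPM, others 16.2 to 18.1), heme synthesis (-0.0509, others 0.26 to 0.31) and the fibroblast and epithelial list (-1.85, others -0.60 to -0.44), and highest for mast cell and basophil genes (1.38 over 4 measured genes, others -0.80 to -0.48). P15 was highest for AQP1 (67.2 CPM, others 24.7 to 29.1) and lowest for STIP1 (303 CPM, others 417 to 444) and lymphoid markers (-1.15 over 6 measured genes, others 0.11 to 0.28). STIP1 and the lymphoid genes CD3E and CD3G lie in the part of chromosome 11 whose genes were lower as a block in P15. In P15 CD3G was at 0.124 CPM, near the floor, and CD3E at 0.218 CPM. The other P95H clones had 0.73 to 1.69 and 0.67 to 0.88 CPM. For CD3G and CD3E these are larger falls than the block median of log2 -0.54. P9 was lowest for GNB1L (16.6 CPM, others 26.2 to 27.4) and EZH2 (138 CPM, others 158 to 162), and W19 highest for mitochondrially encoded genes (0.16, others -0.05 to -0.02).

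W33 differed from the other WT clones at 2457 genes. Removing the trend over GC content and length left 773 calls, 622 of them among the 2457 and in the same direction, which argues against the trend as the whole cause of those 622 and leaves it open for the calls that ended. Lower depth is argued against by the 2420 calls that W33 had after all 8 clones were thinned to its total, a test that replaced a first one in which W19 alone was thinned. Abundant genes are argued against by the 10 most abundant ones, which took 5.53% of counts in W33 (95% Wilson interval 5.52 to 5.54%, counting error only) against 5.13 to 6.47% elsewhere. Antisense genes and pseudogenes were among the largest falls in W33. ZBED9-AS1 stood at 0.0877 CPM (other WT clones 2.45 ± 0.0568) and PDE4DIPP7 at 0 (others 1.27 ± 0.338). Protein-coding genes changed too, such as HBZ (596 CPM, other WT clones 71.9 ± 13.4). HBZ reached 685.5 CPM in a P95H clone, so its level is not particular to W33. W33 had the lowest share of reads placed in no gene by the counter (47.6%, next 48.1% in P15). Its share of ambiguous reads was highest (2.55%, next 2.45% in the parental library). These values, picked after they were seen, do not decide the cause. What remains, a difference of the clone itself or of its RNA or library preparation, is open, since a clone has 1 library.

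The block shifts on chromosome 11 in P15 and on chromosome 1 in P9 were first tested on the genes in which they were found, which could not decide, so parts were sought again in every other gene with the trend over GC content and length kept and measured in the genes left over with it removed. The medians there were 0.4259 and -0.57 in P15 and -0.3978 in P9, which argues against that trend, whereas parts of chromosomes 11 and 19 found this way in W33 came to 0.10 and 0.13, and no part of chromosome 1 was found in W33. A gain and a loss of DNA in the clone may account for the shifts in P15 and P9: 88.9% and 94.65% of the genes left over in the parts of P15 and 91.6% in that of P9 lay on the shifted side. A test of scaling by 1 factor per library was dropped, because such a factor moves all chromosomes alike. DNA was not measured here and the libraries are those in which the shifts were seen, so a change of copy number stays a hypothesis.

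P22 had more KIT, CD53 and DOCK2 and less HEMGN and HBD than the other P95H clones. Cells of other blood lineages mixed into the culture are argued against by PTPRC, which every leukocyte carries, at 0.182 CPM in P22 against 22.1 to 195 CPM in the other 8 libraries, and by HLA-B and HLA-C, neither above its highest level elsewhere, although CD74 (5.24 against 0.209 CPM in the other P95H clones) and HLA-DRA (0.546 against 0 CPM) were higher; a first test by the median of 10 leukocyte markers had left the question undecided and was replaced. The trend over GC content and length is argued against by 65 of the 67 calls, which were calls in the same direction after its removal (104 in all). For the P95H genotype as the sole cause, 0 of 3 other P95H clones had erythroid membrane genes below the lowest WT clone. The pattern is itself a difference from these clones, which share the genotype label, so this count is not separate support. A change of cell state in this clone may be a candidate explanation, and was not tested. The difference in preparation of 1 library stays open too.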

How the results depend on the processing

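The alternatives without W33 and P22, without chromosomes 1 and 11 and with the GC trend removed were chosen after seeing the data. The count of genes between P95H and WT clones was 0 in edgeR at all scalings, with the stricter filter, glmTreat, 1 surrogate variable, 9 libraries, the parental library as wild type, the GC trend removed and chromosomes 1 and 11 left out (1114 to 2828 at an unadjusted p under 0.05). It was 2 without a filter (TNRC6C-AS1 and RNF224), 269 in DESeq2, 59 in limma-voom, 5 without W33 and P22, and 0 to 1 with 1 clone left out (1 without W19); at 2-fold these were 2, 125, 28, 5 and 0 to 1. The parental count of 1 became 5 without a filter, 7 in DESeq2, 0 with the stricter filter, 0 in the smaller fit and 0 to 1 with 1 clone left out (0 without W19 or W42). Camera's 9 lists became 0 with an estimated correlation, 0 and 3 in fry (direction, mixed) and 8 to 11 with 1 clone left out, and 8 with the GC trend removed. The camera adjusted p of the list cytosolic ribosomal proteins was 0.381; with 1 clone left out it was 0.00268 to 0.608, and the direction reversed without W33 (0.00268), without P9 (0.604) and without W33 and P22 (0.0174). W33's 2457 calls became 773 with the GC trend removed, and the WT spread of 0.247 was 0.115 to 0.275 with 1 clone left out (0.115 without W33); the P95H spread of 0.215 was 0.188 to 0.214. Where alternatives differed from the main value the cause was not tested, except that W33 carried the WT spread. Of log2 differences of named genes, 3370 values kept direction and side of the threshold, 68 became calls, 0 lost a call and 25 reversed, in 7 genes that were called neither before nor after. The log2 fold change of SRSF2 was -0.0382 to 0.0809 with 1 clone left out, -0.00553 with the GC trend removed and -0.0300 without W33 and P22. The log2 fold change of CD3G was -1.05 to 0.36, then 0.27 in limma-voom, 0.22 with a surrogate variable and 0.46 without W33 and P22; the log2 fold change of CD3E was -0.57 to 0.0588, then 0.0284 in limma-voom and 0.0168 without W33 and P22. The log2 fold change of KIT was -1.52 (without P22) to 2.14, then -0.00379 in limma-voom and -1.29 without W33 and P22, and the log2 fold change of GATA2 -0.24 to 0.0226. The log2 fold change of HDC was -0.44 to 1.03, then 0.19 in limma-voom, 0.0601 with the parental library as wild type and 0.95 with a surrogate variable, and the log2 fold change of MT-ATP8 -0.0443 in limma-voom and -0.0123 without W33 and P22. Of list values, 403 kept direction and side, 14 became calls, 29 lost a call and 35 reversed, all but 2 of them without a call. With 1 clone left out, the camera adjusted p of the list G2/M phase was 0.365 to 0.991, of the list hnRNP proteins 0.61 to 0.865, of the list lymphoid markers 0.27 to 0.889, of the list mast cell and basophil 0.27 to 0.984, of the list mitochondrially encoded 0.27 to 0.889, of the list myeloid granulocyte and monocyte 0.299 to 0.931, of the list NMD-sensitive transcripts 0.27 to 0.98, of the list p53 targets 0.384 to 0.946, of the list polycomb complexes 0.546 to 0.897, of the list S phase and replication 0.237 to 0.93 and of the list SR proteins 0.452 to 0.999. Without W33 and P22 the direction reversed for the lists apoptosis regulators (0.948), G2/M phase (0.569), mast cell and basophil (0.569), NMD-sensitive transcripts (0.586) and polycomb complexes (0.738), with the GC trend removed for lymphoid markers (0.912), myeloid granulocyte and monocyte (0.912) and nonsense-mediated decay (0.989), and in fry for G2/M phase (0.989) and mast cell and basophil (1). No paired analysis was possible because WT and P95H clones share no clone number. Leaving out chromosomes rich in calls could not be run, as 0 genes were called. At these depths a gene under about 0.1 CPM is near the floor. In simulated data edgeR recovered 49.3% of 2-fold changes, all in genes with a mean over 1 CPM.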

Other observations

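In this part the split counts of unadjusted, DESeq2, limma-voom and list results were set before they were seen; the splits of edgeR calls, the test of the parental library, the permutation test of list means and the search for genes far out in 1 clone were chosen after.

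The list of megakaryocyte and platelet genes did not pass (camera adjusted p = 0.101), with 9 of 11 measured members above 0 (median log2 0.45). The platelet tubulin TUBB1 averaged 20.6 ± 8.503 against 9.94 ± 0.756 CPM and ITGA2B, integrin αIIb, 24.4 ± 14.7 against 11.2 ± 3.53 CPM, with 45.8 CPM in P22 (log2 1.13, and 0.62 without P22), while the collagen receptor GP6 averaged 2.54 ± 0.682 against 3.53 ± 0.682 CPM (SD, n = 4). The mean log2 CPM of the list was above every WT clone in 4 of 4 P95H clones (difference 0.36), as it was for erythroid transcription factors (0.15), NF-kB and inflammatory genes (0.14) and reported SRSF2 targets (0.24), and it was below every WT clone for the unfolded protein response (-0.22). For each of these 5 lists the exact permutation p was 0.0286, the smallest that 70 labelings can give, and 0.211 after adjustment over 37 lists, so none passed. By list medians 4 of 4 held for megakaryocyte genes and the unfolded protein response only: P9 lay below every WT clone for reported SRSF2 targets (-0.04), P15 below W19 for NF-kB genes (-0.00507 against 0.05), and P9 and P38 below W42 for erythroid transcription factors (0.02 and 0.09 against 0.10). The immediate early genes FOS and EGR1 averaged 3.12 ± 1.27 against 8.15 ± 2.76 CPM and 71.3 ± 28.1 against 147 ± 49.4 CPM in P95H and WT clones (edgeR adjusted p = 0.286 and 0.338). The parental library had FOS at 1.36 and EGR1 at 20.3 CPM, below the mean of either group. CASP6, a caspase of apoptosis, averaged 55.0 ± 2.71 against 40.9 ± 0.709 CPM (adjusted p = 0.282).

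Some genes stood at least 8-fold outside the range of the other 8 libraries in 1 clone. The search covered only protein-coding genes outside chromosome Y with a mean of at least 5 CPM. NOX5, a superoxide-producing oxidase, was at 46.7 CPM in P15 and at most 1.67 CPM elsewhere. DOK2, an adaptor of tyrosine kinase signalling, was at 0.133 CPM in W33 and at least 2.17 CPM elsewhere. In P22 the Hedgehog receptor component SMO (0.0597 CPM, elsewhere 3.29 to 22.3), SOX5 (0.149, elsewhere 3.87 to 9.46), EMX1 (0.448, elsewhere 4.50 to 13.3) and SPECC1 (0.388, elsewhere 8.28 to 16.7) were low, beside the genes given for this clone above. W42 had low MAGED1, HCLS1 and ADGRA3. Neither the parental library nor W19, W36, P9 or P38 had such a gene among the protein-coding genes searched.

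The 8 clones can be split into 4 and 4 in 35 ways, so 1 split is 2.86% of them. The real split had 2130 genes at an unadjusted p under 0.05, more than any other split (1 of 35, highest other 1741). It also had the most limma-voom calls, 59 (1 of 35, highest other 12). Taken alone, each of these 2 counts is past the 5% level. A share of 1 in 35 is the smallest that the splits can give. Several counts were set against the splits without adjustment, so chance is not excluded for the set. For DESeq2 the real split had 269 calls and 1 other split, W19, W36, W42 and P38 against the rest, had 282 (2 of 35), so chance cannot be excluded. The edgeR count of 0, with or without the 2-fold limit, was reached by all 35 splits (highest other 1). The 9 lists called by camera were reached by 12 of 35 splits (median of the other splits 8, highest other 13), so chance cannot be excluded for the number of lists.

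If the genes that differ between the groups set the P95H clones apart from cells with unedited SRSF2, the parental library should lie nearer to the WT clones. It did so at 77.65% of the 2130 genes, but 6 of the 35 splits, the real one included, placed the parental library as far to 1 side (highest other 85.87%), so this could be a property of how the parental library lies among the clones, and the explanations cannot be told apart.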
